A study of Mus musculus with 6 samples.

How the data were processed

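The series holds 6 Affymetrix Mouse Gene 2.0 ST arrays of skeletal muscle RNA, 3 from floxed Sidt2 mice without Cre and 3 from floxed mice carrying a Cre transgene under the muscle creatine kinase promoter. Per the labels' protocols, total RNA was purified with a column kit and a DNase step, and biotinylated cDNA was made from 250 ng of it. The labels number 3 samples per genotype and speak of mice, without stating that each array is a separate animal, so p-values measure the spread between these samples.

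The values used are the log2 signals the authors deposited, made with the RMA method in Affymetrix Expression Console at gene level on the full probe set list, per the file headers and the submitters' processing notes. Versions of these tools are not given in the sources used here. As a method, RMA subtracts a background, forces the arrays to 1 distribution by quantile normalization and summarises the probes of a set by median polish, so a shift common to all genes of an array is removed before any value is seen. The annotated table and the series matrix hold the same values for all 41345 probe sets, to within 1e-9. Arrays have no read depth, and their number limits the precision.

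Gene names come from the annotated table. It gives 1 symbol for 24724 probe sets, several for 2313 and none for 14308. Of 23385 distinct symbols 20202 were current in the RefSeq gene table of GRCm38.p6, 2132 were updated through a synonym and 1051 were kept as printed. The headers name no genome build for the positions, but 98.0% of 23591 probe sets overlapped the gene of their symbol in GRCm38.p6. No genome sequence was used here. For each of 23352 genes the probe set with the highest mean over the 6 arrays was taken, from those with exactly 1 symbol. A gene was tested if its signal exceeded the array's median of non-control probe sets on at least 3 of the 6 arrays, whatever the genotype, which left 13661. The table flags cross-hybridisation for 23 of the called genes. Of 144 other tested probe sets of called genes 18 changed in the opposite direction.

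Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without covariates, 4 residual and 4.70 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this fit unless another is named. Errors are the moderated standard error of the log2 change or the SD of 3 arrays. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 39 of 44 lists with at least 5 tested members, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction. The 44 lists (30 of pathways or gene classes, 14 of cell types or sex), the comparison, its test and the alternatives were fixed before the data were examined. Genes were named by a rule fixed at the same time. It takes Sidt2, the 12 largest rises and 12 largest falls among genes that passed and whose genotypes did not overlap (leaving out predicted genes, receptors of smell, small RNAs and immune receptor segments), up to 4 members with the smallest p of each list, and Sqstm1, Map1lc3a, Map1lc3b, Lamp1, Lamp2, Ctsd, Ctsl, Tfeb and Sidt1. Some genes that the rule takes are not reported here. A gene that falls outside it was chosen after its values were seen, which holds for Cx3cr1, Cd163 and the genes first named under the additional observations.

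The fit was tested on simulated arrays with the means and spreads of the 13661 genes, with known changes given to some. It found 14 of 67 genes changed by 0.5 on the log2 scale, 65 of 67 changed by 1 and 66 of 66 changed by 2, with 13 false calls among 158. On simulated lists 4 of 4 shifted by 0.4 were found, with 0 false calls among the rest of the 39. Changes of 0.5 were thus often missed in this simulation. It held far fewer changed genes than the 1929 called in the data, which makes the adjusted threshold stricter. The share found there therefore does not carry over to the data.

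The alternatives were no filter and a filter at the 75th percentile, every probe set or the mean of a gene's probe sets, a further quantile normalization, centring each array on its median, the series matrix values, an intensity trend with a robust prior, array weights, the replicate number as a block, other thresholds (adjusted p under 0.1, unadjusted p under 0.05 with 1.5-fold or 2-fold), a test without moderation, and each array left out in turn. Leaving out control 1 and knockout 3 together was added after seeing the data. Enrichment of Gene Ontology terms, from the annotated table's own columns, was tested with a one-sided hypergeometric test against the tested genes with a term (SciPy 1.17.1, Python 3.11.15), for 1149 terms of 15 to 400 tested genes per direction, with Benjamini-Hochberg adjustment. Correlations and permutations over genes used exact enumeration or 100000 resamples. Figures were drawn with matplotlib 3.10.9.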

Results

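Skeletal muscle of 2-month-old mice was profiled on 6 Affymetrix whole-transcript gene arrays. Sidt2 encodes a multipass membrane protein of the lysosome that has been linked to the transport of RNA and DNA into this organelle. For 3 samples the mice were muscle-specific Sidt2 knockouts, from a cross of floxed animals with a line that makes Cre recombinase under the muscle creatine kinase promoter, and 3 samples from floxed mice without Cre served as controls. The labels number the samples within each genotype but name neither the muscle dissected nor the sex, and do not state that each sample is a separate animal. Signals were on a log2 scale, and the median of the 34365 non-control probe sets lay between 2.52 and 2.58 on the 6 arrays, against 2.11 to 2.18 for the 23 antigenomic background probe sets. After 1 probe set was kept per gene, 13661 of 23352 genes were above the filter on low signal and were tested. The number of arrays, 3 per genotype, limits the precision of every value.

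The comparison asked which transcripts differ between muscle of Sidt2 knockouts and of floxed mice without Cre. No group carried Cre without floxed Sidt2, so effects of Cre and of Sidt2 loss cannot be told apart. The macrophage genes Ctss and Cd68, the embryonic muscle genes Mymk and Sln, the chaperone Hspa5 of the endoplasmic reticulum and the matrix gene Postn were higher in knockout muscle, whereas Pfkfb3, the calcium channel gene Ryr1 and the muscle gene Cmya5 were lower. In total 1929 genes passed adjusted p under 0.05 in limma, 1109 of them higher and 820 lower in the knockout. At least 2-fold changes were seen in 382 of the higher and 54 of the lower genes. The 3 arrays of each genotype did not overlap for 1928 of the 1929 genes, and for 34.8% of all tested genes, where chance gives 10%. Correlations between arrays of 1 genotype ranged from 0.982 to 0.988 and those between genotypes from 0.949 to 0.977 across genes. The first principal component held 62.7% of the variance, and separated the genotypes. The control arrays 1 to 3 lay at -29.0, -17.0 and -27.9 and the knockout arrays 1 to 3 at 18.3, 37.4 and 18.3. The count fell to 765 genes without control 1, 1011 without control 3, 1070 without knockout 2 and 1280 without knockout 3, and the lower genes alone to 537 without control 2. It was 99 in a test without variance moderation and 84 without both control 1 and knockout 3. That omission was chosen after seeing the data because these arrays carried signal of the brown fat gene Ucp1. The calls of most of the 1929 genes ended in both settings. With only 2 arrays per genotype left, lost power alone lowers the count, and no other pair was left out for comparison. All 84 genes were among the 1929 and kept their direction.

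**Figure D1:**
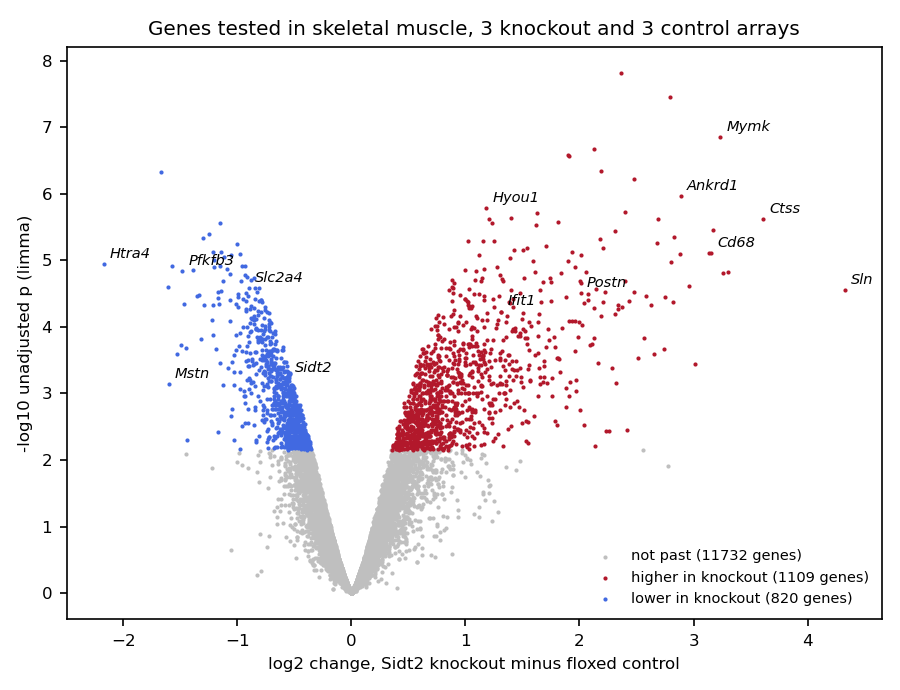
Each point is 1 of the 13661 genes tested, with the log2 change between 3 Sidt2 knockout and 3 floxed control arrays on the x axis and -log10 of the unadjusted limma p on the y axis. The 1109 genes in red and 820 in blue passed adjusted p under 0.05, and the rises reach 4.33 (Sln) while the falls reach -2.17 (Htra4).

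Sidt2 was read by 1 probe set (17526583, chromosome 9, positions 45937857 to 45955249 on the minus strand as the table gives them, with no genome build named). It fell from a log2 signal of 7.24 ± 0.07 (SD, n = 3) to 6.69 ± 0.07 (SD, n = 3), a change of -0.55 (SE 0.10, adjusted p = 0.0123), or 1.46-fold. The control arrays read 7.20, 7.21 and 7.32 and the knockout arrays 6.62, 6.74 and 6.73. The probe set covers the whole gene and the labels do not say which exons were deleted, so its level is not a measure of the deletion and includes RNA of cells without Cre. The fall passed in each of the 6 runs that left out an array (adjusted p from 0.0297 to 0.0451). It missed the threshold without moderation (adjusted p = 0.0558) and without both control 1 and knockout 3 (adjusted p = 0.101), and over all alternatives the adjusted p ranged from 0.0077 to 0.101. Its paralogue Sidt1 lay below the filter, at 2.47 ± 0.045 in controls and 2.53 ± 0.182 in knockouts (SD, n = 3).

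The largest rise was that of Sln, which encodes sarcolipin, a small inhibitor of the sarcoplasmic reticulum calcium pump, from 3.43 ± 0.50 to 7.75 ± 1.27 (SD, n = 3), or 20.1-fold (adjusted p = 0.0036). Its log2 change of 4.33 was 3.59 without knockout 1, below that of Ctss (3.80) on the same arrays. Mymk, which encodes the myoblast fusion protein myomaker, rose 9.40-fold (log2 change 3.23, SE 0.21, adjusted p = 6.21e-04), and Ankrd1, a stress-responsive ankyrin repeat protein of the sarcomere, rose 7.40-fold (2.89, SE 0.24, adjusted p = 0.0015). The other 9 of the 12 largest rises were Ctss (12.2-fold), Lilrb4a (9.89-fold), Ms4a6c (9.56-fold), Mpeg1 (9.03-fold), Cd68 (8.88-fold), the chemokine Ccl8 (8.79-fold), the proton pump subunit Atp6v0d2 (8.07-fold), Ly86 (7.79-fold) and Cd84 (7.37-fold), with adjusted p from 0.0019 to 0.0098. Ctss, Mpeg1 and Cd68 belong to the list of macrophage markers. All 12 passed in each of the 6 runs that left out an array, and the log2 change of Atp6v0d2 went from 3.01 to 2.41 without knockout 2. The control means of Atp6v0d2 (2.71) and Mymk (2.98), among others, lay near the array medians of non-control probe sets, where background can compress a fold.

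Among the falls, Htra4, a serine protease gene, led with 6.03 ± 0.57 against 3.85 ± 0.035 (SD, n = 3), or 4.51-fold lower (adjusted p = 0.0028). Ppp1r1a, which encodes an inhibitor of protein phosphatase 1, was 3.04-fold lower (adjusted p = 0.0035), and Mstn, which encodes the muscle growth inhibitor myostatin, was 3.04-fold lower (adjusted p = 0.0137, and 0.0563 without control 1). Mrln, which encodes myoregulin, a further inhibitor of the calcium pump, was 2.76-fold lower (adjusted p = 0.0039), opposite in direction to Sln. Pfkfb3, which encodes an enzyme that sets the level of the glycolytic activator fructose 2,6-bisphosphate, was 2.79-fold lower (adjusted p = 0.0029). The other falls were those of Gpcpd1 (2.98-fold), Fgfbp1 (2.81-fold), Dkk3 (2.72-fold), Ttll7 (2.62-fold), Smox (2.56-fold), Adhfe1 (2.52-fold) and Mettl11b (2.50-fold), with adjusted p from 0.0028 to 0.0413. The knockout mean of Fgfbp1, 2.51, lay near the array medians of non-control probe sets, where background can compress a fold. Dkk3 passed only without control 3 among the 6 runs that left out an array, with adjusted p from 0.0691 to 0.106 in the others, and missed the threshold without the filter (adjusted p = 0.0572), with an intensity trend and robust prior (adjusted p = 0.0687), without moderation (adjusted p = 0.219) and without both control 1 and knockout 3 (adjusted p = 0.119).

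**Figure D2:**
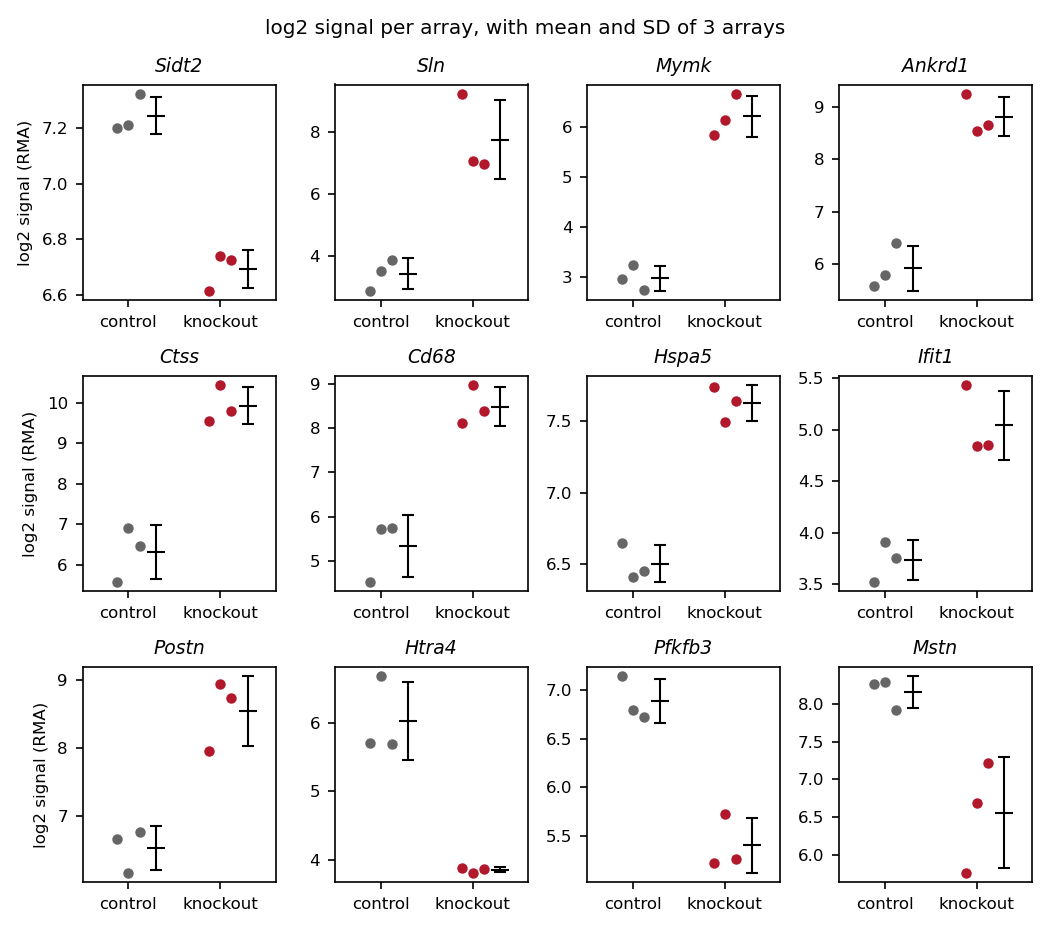
Log2 signal (RMA, y axis) of 12 genes on each of the 3 floxed control (grey) and 3 Sidt2 knockout (red) arrays, with the mean and SD of the 3 arrays as a black bar; each panel has its own y range and none starts at 0. The genotypes do not overlap for any of the 12 genes, and Sidt2 moves by -0.55 while Sln moves by 4.33.

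Lysosomal hydrolases rose and none fell. Of 46 tested members 24 were higher over all genes and 29 when adjusted over the list alone, with a median log2 change of 0.60 (camera with a preset correlation, adjusted p = 1.26e-11, and adjusted p = 0.398 with an estimated correlation). Beside Ctss, the rises included the asparaginyl endopeptidase Lgmn (1.90, SE 0.21, adjusted p = 0.0027), the hexosaminidase subunit Hexa (1.42, SE 0.19, adjusted p = 0.0038) and cathepsin Z, Ctsz (1.15, SE 0.17, adjusted p = 0.005). Ctsl rose by 1.03 (SE 0.19, adjusted p = 0.0117, and 0.0515 without control 1) and Ctsd by 0.42 (SE 0.11, adjusted p = 0.0414, and 0.0842 to 0.119 on leaving out any array but knockout 1). The macrophage markers described further on had a median log2 change of 1.91 in the same arrays, and Ctss is in both lists.

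The other lysosomal and autophagy lists had medians nearer to 0. Of 25 lysosomal membrane proteins 6 were higher and 2 lower (9 and 3 adjusted over the list alone). Cd63 rose by 1.15 (SE 0.14, adjusted p = 0.0031). The cholesterol carrier Npc2, a soluble protein that this list also holds, rose by 1.06 (SE 0.18, adjusted p = 0.0087). Lamp2 was at 0.52 (SE 0.14, adjusted p = 0.0395, and 0.0897 to 0.111 on leaving out any array but knockout 1) and Lamp1 at 0.18 (SE 0.13, adjusted p = 0.379). The list as a whole did not pass (median 0.13, or 0.07 without knockout 2, camera adjusted p = 0.0662), but it did without control 3 (adjusted p = 0.0253) or knockout 1 (median 0.21, adjusted p = 0.0264), and with no filter (adjusted p = 0.01). Of 18 subunits of the vacuolar proton pump 4 were higher, and adjusted over the list alone 4 were higher and 1 lower. Their median was 0.21 (camera adjusted p = 0.0286, and adjusted p = 0.398 with an estimated correlation), and the list missed the threshold without control 2 (adjusted p = 0.0536) or with a filter at the 75th percentile (adjusted p = 0.0647). Atp6v0d2, a subunit isoform typical of macrophages and osteoclasts, had by far the largest value of this list. Of 45 autophagy genes 7 fell and none rose (7 lower and 1 higher adjusted over the list alone). Among them were Atg9a, which encodes a membrane carrier of the forming autophagosome (-0.78, SE 0.12, adjusted p = 0.0062), and the initiating kinase Ulk1 (-0.75, SE 0.13, adjusted p = 0.0098). The list median was -0.07 (camera adjusted p = 0.121), and fry passed downward (adjusted p = 0.0211). The receptor Sqstm1 was at 0.20 (SE 0.11, adjusted p = 0.255), Map1lc3a at 0.10 (SE 0.19, adjusted p = 0.757), Map1lc3b at -0.10 (SE 0.11, adjusted p = 0.619) and the lysosomal transcription factor Tfeb at -0.26 (SE 0.12, adjusted p = 0.179). The signal of Tfeb, 3.07 in controls and 2.81 in knockouts, lay near the array medians of non-control probe sets, so a change could be hidden.

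Macrophage markers shifted more than any other list. Of 25 tested, 23 rose, 24 adjusted over the list alone, with a median log2 change of 1.91 (camera adjusted p = 1.53e-20, and adjusted p = 0.339 with an estimated correlation). Fcgr1, a high-affinity antibody receptor, rose by 1.90 (SE 0.13, adjusted p = 6.21e-04) and the galectin Lgals3 by 1.91 (SE 0.14, adjusted p = 6.21e-04), whereas Cx3cr1 was at 0.41 (adjusted p = 0.324) and Cd163 at 1.21 (adjusted p = 0.105). The mean of the 25 markers was 4.31, 5.01 and 4.53 on control arrays 1 to 3 and 6.18, 7.08 and 6.45 on knockout arrays 1 to 3. Of the fibro-adipogenic progenitor markers 2 of 14 rose (4 adjusted over the list alone), led by Lum (2.84-fold, adjusted p = 0.0045), with a list median of 0.52, or 0.29 without knockout 2 (camera adjusted p = 2.14e-04, and adjusted p = 0.472 with an estimated correlation). Adipocyte markers had 1 rise among 15 (0 adjusted over the list alone), Cebpa (adjusted p = 0.0441, and 0.0796 to 0.125 on leaving out any array but control 1). Their median was 0.47 (camera adjusted p = 0.0389, and adjusted p = 0.716 with an estimated correlation). That list's call ended without control 2, control 3, knockout 1 or knockout 2 (adjusted p from 0.0536 to 0.284), with arrays centred (adjusted p = 0.0508) and with array weights (adjusted p = 0.105). Its median was 0.22 without control 3, 0.92 without control 1 and 0.99 without both control 1 and knockout 3 (adjusted p = 6.71e-07).

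Both lists of vascular markers shifted downward with a preset correlation, beside a macrophage marker median of 1.91, though most of their members did not pass. Of 16 endothelial markers 4 fell (6 adjusted over the list alone), with Kdr, the main receptor for vascular endothelial growth factor, at -1.03 (SE 0.19, adjusted p = 0.011) and a list median of -0.26 (camera adjusted p = 0.0042, and adjusted p = 0.299 with an estimated correlation). Of 12 smooth muscle and pericyte markers Abcc9 alone fell, also when adjusted over the list alone (adjusted p = 0.0189 over all genes, and 0.05 to 0.0671 without control 1, control 3, knockout 1 or knockout 2). The list median was -0.18, or -0.27 without control 2 (camera adjusted p = 0.0222, and adjusted p = 0.41 with an estimated correlation). The call ended without control 3 (adjusted p = 0.155) or knockout 1 (adjusted p = 0.0536) and with a filter at the 75th percentile (adjusted p = 0.0649). Markers of tenocytes (0 of 9 past), satellite cells (2 of 12 higher), Schwann cells and nerve (1 of 9 higher, Ncam1, which fibres also express) and keratinocytes (0 of 5) did not pass as lists, with camera adjusted p of 0.704, 0.759, 0.759 and 0.757. Adjusted over the list alone, these counts were the same. The satellite cell (-0.01 and 0.06) and nerve lists (-0.05 and 0.09) had a median and a mean that differ in sign, and both tests pointed up. Both medians were above 0 without control 3 or knockout 1. Too few markers of neutrophils (3), lymphocytes (4), brown adipocytes (4) and erythrocytes (2) and too few sex-linked genes (4) were tested for a list test. In these lists the neutrophil gene Retnlg rose 2.83-fold (adjusted p = 0.0143, and 0.06 without control 1), the lymphocyte gene Il7r rose by 1.88 (adjusted p = 0.0214, and 0.0524 to 0.0829 without control 1, control 2 or knockout 3) and Ppargc1a fell. Retnlg was above the filter in only 3 of the 6 runs that left out an array, and passed in 2 of these. Adjusted over the list alone, 2 neutrophil markers were higher and 1 erythrocyte marker was lower, and the other counts were the same.

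Genes of innate immunity and matrix rose beside the macrophage markers, whose median was 1.91. Of 26 interferon-stimulated genes 14 rose (23 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 3.95e-11, and adjusted p = 0.339 with an estimated correlation). They included Ifit1 (1.31, SE 0.18, adjusted p = 0.0044), Bst2 (1.46, SE 0.23, adjusted p = 0.0064) and Oasl2 (1.61, SE 0.27, adjusted p = 0.0087). Of 18 nucleic acid sensing genes 10 rose (13 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 2.11e-06, and adjusted p = 0.339 with an estimated correlation). The endosomal RNA receptors Tlr7 (1.59, SE 0.18, adjusted p = 0.0027) and Tlr8 (1.83, SE 0.34, adjusted p = 0.0111) were among them, as were the RNA-editing enzyme Adar (0.61, SE 0.11, adjusted p = 0.0112) and the RNA-activated kinase Eif2ak2 (0.64, SE 0.12, adjusted p = 0.0113). Of 36 extracellular matrix genes 18 rose (26 adjusted over the list alone), including Postn (2.01, SE 0.26, adjusted p = 0.0037) and Bgn (1.28, SE 0.18, adjusted p = 0.005), with a median of 0.82 (camera adjusted p = 1.26e-11, and adjusted p = 0.398 with an estimated correlation).

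Genes of embryonic and regenerating muscle rose as a list. Of 22 tested, 8 rose and Dkk3 fell, with the same counts adjusted over the list alone, and the median was 0.30, or 0.62 with a filter at the 75th percentile and 0.16 without both control 1 and knockout 3 (camera adjusted p = 0.0039, and adjusted p = 0.345 with an estimated correlation). Besides Mymk and Sln, the fetal troponin Tnnt2 rose by 2.40 (adjusted p = 0.0019) and the embryonic light chain Myl4 by 1.65 (adjusted p = 0.0036), while the macrophage marker median was 1.91. Of 17 genes of the denervation response 5 rose and 2 fell (7 and 2 adjusted over the list alone). The acetylcholine receptor subunit Chrna1 was at 1.54 (SE 0.16, adjusted p = 0.0024), Ncam1 at 1.68 (SE 0.20, adjusted p = 0.0031), the myogenic factor Myog at 1.14 (SE 0.21, adjusted p = 0.0113) and Fgfbp1, a gene that helps maintain the neuromuscular junction, at -1.49. The list did not pass (camera adjusted p = 0.217), and its median of -0.01, which was 0.01 with arrays centred, and mean of 0.28 differ in sign. Of 22 atrophy genes 5 rose and 3 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.759, median -0.06 and mean 0.29). The metallothioneins Mt2 (2.68, adjusted p = 0.0024) and Mt1 (1.83, adjusted p = 0.0029) were among the rises, and Fbxo32, the ubiquitin ligase atrogin, fell by 0.73 on the log2 scale (adjusted p = 0.0123). Of 20 muscle growth signalling genes 2 rose, Metrnl (0.90, adjusted p = 0.0075) and Fstl1 (1.05, adjusted p = 0.0252, and 0.0542 to 0.0899 without control 1, control 3 or knockout 3), and 2 fell, Mstn among them, with the same counts adjusted over the list alone (camera adjusted p = 0.78).

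Stress genes of the endoplasmic reticulum rose with none falling. Of 25 tested, 15 passed over all genes and 20 adjusted over the list alone, with a median of 0.69 (camera adjusted p = 8.38e-14, and adjusted p = 0.299 with an estimated correlation). The chaperones Hyou1 (1.18, SE 0.10, adjusted p = 0.0019), Hspa5 (1.12, SE 0.12, adjusted p = 0.0024) and Hsp90b1 (1.02, SE 0.10, adjusted p = 0.0024) and the disulphide isomerase Pdia6 (1.21, SE 0.11, adjusted p = 0.0019) rose 2.03- to 2.31-fold, while the macrophage marker median was 1.91. Within genotypes, the array means of these 25 genes and of the macrophage markers had a Pearson's r of -0.215 over the 6 arrays. Of 22 genes of the integrated stress response 7 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0098, and adjusted p = 0.398 with an estimated correlation). This call ended without knockout 1 (median 0.32, adjusted p = 0.0536), without both control 1 and knockout 3 (adjusted p = 0.0517) and with a filter at the 75th percentile (adjusted p = 0.346). Mthfd2, a mitochondrial folate enzyme, rose by 1.75 (adjusted p = 0.0031) and the amino acid carrier Slc7a5 by 1.23 (adjusted p = 0.0101), whereas Chac1, a glutathione-degrading enzyme, was at -1.03 (adjusted p = 0.0087) and Vldlr at -0.73 (adjusted p = 0.0055).

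Other stress and signalling lists held fewer calls, beside the macrophage marker median of 1.91. Of 19 immediate early genes 5 rose (6 higher and 1 lower adjusted over the list alone), among them Egr1 (1.33, adjusted p = 0.0031) and Fos (0.86, adjusted p = 0.008), with a median of 0.32 (camera adjusted p = 0.0029, adjusted p = 0.299 with an estimated correlation, and 0.0583 with a filter at the 75th percentile). Of 21 p53 targets and apoptosis genes 7 rose, also when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0338, and adjusted p = 0.339 with an estimated correlation). They included Btg2 (0.90, adjusted p = 0.0088). The list's call ended on leaving out any array but control 3 (adjusted p from 0.0511 to 0.215, with a median of 0.05 without knockout 2), without both control 1 and knockout 3 (adjusted p = 0.264) and with a filter at the 75th percentile (adjusted p = 0.0896). Of 17 circadian clock genes 3 fell (5 adjusted over the list alone), Bhlhe41 by 0.61 on the log2 scale (adjusted p = 0.0136), with a median of -0.28 (camera adjusted p = 5.2e-04, and adjusted p = 0.299 with an estimated correlation). Lists of NRF2 antioxidant genes (2 of 21 higher, Gpx1 at 1.02 and Hmox1 at 1.28), heat shock genes (3 of 19 higher and Dnajb5 at -0.82), proteasome subunits (1 of 32 higher, 1 lower), lipid synthesis and storage (1 of 21 higher, 2 lower, among them Acacb at -0.82) and cholesterol synthesis (2 of 21 lower, among them Hsd17b7 at -0.76) did not pass, with camera adjusted p of 0.706, 0.217, 0.757, 0.394 and 0.759. Adjusted over the list alone the heat shock list had 3 higher and 2 lower genes, and the counts of the others were the same. The heat shock list passed without knockout 2 (adjusted p = 0.0367). The lipid list had a median of -0.04 and a mean of 0.0022, and the cholesterol list a median of 0.05 and a mean of -0.03, while both tests pointed down. These medians changed sign without both control 1 and knockout 3, to 0.10 and -0.01. Of the 14 tested chromosomal neighbours of Sidt2, Il10ra rose (1.08, adjusted p = 0.0037) and Scn4b fell (-0.78, adjusted p = 0.0091), with the same counts adjusted over the list alone (camera adjusted p = 0.394). Il10ra was above the filter in only 3 of the 6 runs that left out an array, and passed in these 3.

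Lists of glucose use, mitochondria and fatty acid oxidation shifted downward with a preset correlation, though most of their members did not pass. Of 27 glycolysis and glucose uptake genes 10 fell and 1 rose (12 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 1.37e-05, and adjusted p = 0.339 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, was at -0.90 (SE 0.11, adjusted p = 0.0036), the glycogen-targeting phosphatase subunit Ppp1r3a at -0.81 (SE 0.13, adjusted p = 0.0069) and the phosphorylase kinase subunit Phka1 at -0.88 (SE 0.15, adjusted p = 0.0095). Of 65 nuclear OXPHOS subunits 7 fell (1 adjusted over the list alone, Cox6a2, at -0.69, adjusted p = 0.0104), with a median of -0.21, or -0.12 without knockout 2 (camera adjusted p = 2.11e-06, and adjusted p = 0.528 with an estimated correlation). Of 26 genes of mitochondrial quality control and biogenesis 6 fell, also when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0026, and adjusted p = 0.398 with an estimated correlation). Among them were the fusion protein Mfn1 (-0.67, adjusted p = 0.0097) and the coactivator Ppargc1a (-0.98, adjusted p = 0.0111). Of 26 fatty acid oxidation genes Ucp3 (-0.89, adjusted p = 0.0041) and Ppard (-0.63, adjusted p = 0.0113) fell, also when adjusted over the list alone, with a median of -0.28 (camera adjusted p = 4.26e-04, and adjusted p = 0.458 with an estimated correlation). Macrophage markers had a median of 1.91 on the same arrays.

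The calcium handling, sarcomere and fast fibre lists also shifted downward with a preset correlation, though most of their members did not pass. Of 21 calcium handling genes 7 fell and none rose, also when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0029, and adjusted p = 0.406 with an estimated correlation). They included the calcium release channel Ryr1 (-0.70, SE 0.11, adjusted p = 0.0066), its coupling protein Stac3 (-0.78, SE 0.12, adjusted p = 0.0067) and the junction protein Jph1 (-0.71, SE 0.13, adjusted p = 0.0118). Of 24 sarcomere and costamere genes 8 fell and 1 rose (9 and 1 adjusted over the list alone). Cmya5 was at -0.74 (adjusted p = 0.0044), and the rise was that of the chaperone Cryab (0.76, adjusted p = 0.0234, and 0.0503 to 0.088 without control 1, control 3 or knockout 3). The list median was -0.26 (camera adjusted p = 0.0039, and adjusted p = 0.472 with an estimated correlation). Of 15 fast fibre genes only Pfkm fell (-0.56, SE 0.10, adjusted p = 0.0101), also when adjusted over the list alone, and the median was -0.19 (camera adjusted p = 0.0043, and adjusted p = 0.472 with an estimated correlation). Slow fibre genes had 1 call in 13 and 0 adjusted over the list alone, with a median of -0.0037 beside a mean of 0.06 (camera adjusted p = 0.706). The call was Tpm3 (0.69, adjusted p = 0.0446), whose probe set the table places on chromosome 14 and not at the Tpm3 gene on chromosome 3. It missed the threshold on leaving out any array but knockout 1 (adjusted p from 0.0667 to 0.13), and with the mean of the gene's probe sets (adjusted p = 0.382). Without control 3, whose slow fibre genes were high, the list median was 0.77 (camera adjusted p = 8.35e-04). The macrophage marker median of 1.91 stands beside these falls too. Over the 39 lists tested, 13 passed upward and 10 downward with the preset correlation, and 0 with an estimated correlation. Of these 23, fry did not call the matrix, integrated stress response, fibro-adipogenic, adipocyte, smooth muscle, sarcomere, OXPHOS and fatty acid oxidation lists (adjusted p from 0.0542 to 0.445). Lists of independent simulated genes shifted by 0.4 were found with both, 4 of 4 each.

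**Figure D3:**
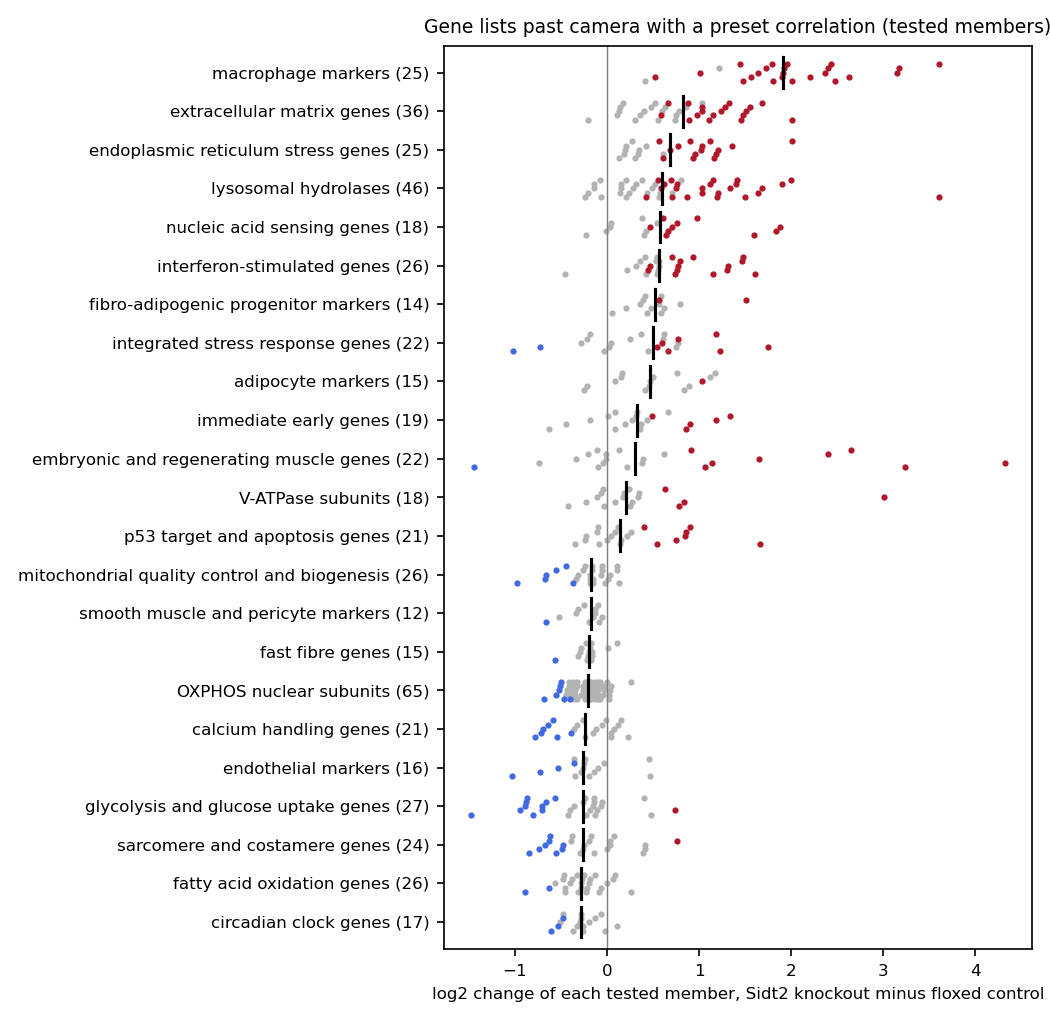
Log2 change (x axis, Sidt2 knockout minus floxed control) of every tested member of the 23 gene lists that passed camera with a preset correlation, with the number of tested members in brackets after each list's name. Red and blue points are genes past adjusted p under 0.05 over all genes, grey points did not pass, and the black bar is the list's median, which runs from -0.28 for circadian clock genes to 1.91 for macrophage markers.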

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

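Of the tests in this part, those of the other lysosome and autophagy lists, of the list medians against contractile genes, of falls beyond the contractile median and both on spike-in controls were chosen only after the results were seen.

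Outside the gene-level comparison, 202 of 1290 probe sets with several gene symbols passed limma's adjusted p under 0.05, 158 of them higher and 44 lower. Among 1770 probe sets with no symbol 26 passed, 17 higher and 9 lower. Of 54 spike-in control probe sets 2 passed, both higher in the knockout, whereas 0 of 1494 intron control probe sets passed (85 at an unadjusted p under 0.05).

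The 1929 genes of the real grouping compare with at most 0 genes in the other splits of the 6 arrays. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each of the other splits mixes the genotypes, so a genotype difference adds to their spread and lowers their counts. Their 0 genes therefore do not show what unrelated groups would give.

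Lysosomal hydrolases rose with the macrophage markers, which include Lyz2, at 8.17 in controls and 10.57 in knockouts. Within genotypes, the array means of the 25 markers and of the 45 hydrolases outside that list correlated over the 6 arrays (Pearson's r = 0.921, Spearman's rho = 0.943, exact one-sided permutation p = 0.0278 for each, the smallest that 36 arrangements allow). The adjusted p over the 38 lists compared was 0.211, r was 0.717 without the 2 arrays farthest from the median of the markers, and lists other than lysosomal ones tracked the markers too, with r of 0.976 for fibro-adipogenic progenitor markers, 0.941 for matrix genes and 0.863 for p53 targets and apoptosis genes. Some other lists that rose did not track them closely. Their r was -0.215 for endoplasmic reticulum stress, -0.663 for embryonic muscle, -0.0661 for immediate early and 0.318 for interferon-stimulated genes. On 6 arrays these values decide no source. A programme that raises all lysosomal and autophagy genes alike would raise the autophagy list too, where 7 of 45 genes were lower and 0 higher over all genes. That list did not pass (camera adjusted p = 0.121). Dilution of fibre RNA, which stays open for list medians in the next paragraph, could mask a rise there. The autophagy list therefore does not decide about such a programme. The hydrolase median lay 0.58 above that of 88 genes of the membrane, proton pump and autophagy lists (permutation p over genes = 1e-05, the smallest the resamples can give). That test treats genes as independent, while the estimated correlation between hydrolases was 0.51, so its p overstates the evidence and decides nothing. RNA of macrophages in the tissue is thus a candidate source of the hydrolase signal that this correlation does not single out, and a rise within fibres after Sidt2 loss stays open beside it, untested.

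The glucose, fatty acid oxidation, OXPHOS and calcium lists passed downward with a preset correlation and not with an estimated one (adjusted p from 0.339 to 0.528), with 10 of 27, 2 of 26, 7 of 65 and 7 of 21 genes lower, while macrophage markers had a median of 1.91 and endothelial markers one of -0.26. Dilution of fibre RNA as the whole cause of the lower genes is argued against by 235 genes that fell beyond the contractile median of -0.21 in limma's treat test at adjusted p under 0.05. These include 49 of the 54 genes lower by at least 2-fold. Those 54 were chosen by the size of their fall, so this count was nearly given in advance and adds no support. In the test set beforehand only 23 of the 54 had a 95% interval wholly below the lowest contractile gene. This was under the share set, so that test did not argue against dilution for those falls. For the list medians dilution stays open, because the 139 metabolic and calcium genes differed from the 37 contractile genes by a median of only -0.015 (permutation p over genes = 0.774). A lower transcription of these genes in knockout fibres was not tested.

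The 2 spike-in control probe sets that passed belong to the class of bacterial and phage hybridisation controls, and went from 5.25 to 6.38 (adjusted p = 0.0029 within the class) and from 3.54 to 4.65 (adjusted p = 0.0105). More of the control mix on the knockout arrays is argued against, because the other 16 probe sets of the class had a median difference of -0.0506 and a highest of 0.20, below the lower 95% bound of 0.55. A hypothesis is that they read RNA of the Cre transgene, as the cre gene of a phage is among the usual hybridisation control transcripts. Both are numbered directly after the 2 brightest probe sets of the class. This arrangement was picked out after the 2 had passed, so its nominal chance of 0.0278 among the 9 dim ones does not test the hypothesis. The question stays open, since the table used here names no transcript for them.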

How the results depend on the processing

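Of the settings in this part, leaving out control 1 and knockout 3 together was chosen after seeing the data. Over the leave-one-out runs the count ranged from 765 to 1528 genes, with 477 to 927 higher and 288 to 601 lower, each from 5 arrays. With both of those arrays left out, and so only 2 per genotype, 84 genes passed (67 higher, 17 lower) and Sidt2 was at -0.59 (adjusted p = 0.101). An adjusted p under 0.1 gave 2941 genes, 1294 of them lower. An unadjusted p under 0.05 gave 444 lower genes at 1.5-fold and, at 2-fold, 462 genes, 405 higher and 57 lower; Sidt2, at -0.55, is too small a change for either. Without moderation 99 genes passed, 33 higher and 66 lower, and Sidt2, again at -0.55, had an adjusted p of 0.0558. Camera with an estimated correlation called 0 lists, and fry 16 of 39. The replicate number as a block gave 2166 genes, and the same-numbered arrays' deviations correlated at -0.0439, 0.253 and 0.0363, so the numbers were not taken as pairs. No named gene or list that passed changed direction. Among lists that did not pass, the medians of denervation, slow fibre, muscle growth, atrophy, lipid, cholesterol, satellite cell, nerve, tenocyte and keratinocyte genes changed sign in at least 1 setting. Named genes kept their side of the threshold in 980 leave-one-out values, lost it in 129 and gained it in 10, against 2438, 323 and 36 in the other settings. For lists these numbers were 217, 13 and 4, and 426, 40 and 2. The cause of these changes was not tested. Non-control signal lay near background, with array medians of 2.52 to 2.58 against 2.11 to 2.18.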

Other observations

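The enrichment tests, the genes named from them and the arrays singled out in this part were chosen after the results were seen. The hypergeometric test treats genes as independent, while genes that share a term can move together. Its p-values can therefore overstate the evidence, and the correlation within terms was not estimated.

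Tubb6, a beta tubulin gene, was 5.14-fold higher (log2 change 2.36, SE 0.12, limma adjusted p = 2.09e-04), the smallest p of all genes. Tubb5 was at 1.29 (SE 0.17, adjusted p = 0.0037) and the weakly expressed Tuba1b was 2.83-fold higher (adjusted p = 0.005), whereas Tuba8 was lower (-0.56, SE 0.10, adjusted p = 0.0112). Genes of protein polymerization, 6 of 15 among the higher genes where 1.26 would be expected, passed the hypergeometric test (adjusted p = 0.0177). Of 21 genes with chemokine activity 8 were higher (1.76 expected, adjusted p = 0.00509), including Ccl9 (2.31, SE 0.32, adjusted p = 0.0045) and Ccl5 (1.94, SE 0.21, adjusted p = 0.0024), beside the macrophage marker median of 1.91. Parts of the ribosome were also enriched, with 9 of 20 genes of the small subunit (1.67 expected, adjusted p = 8.45e-04) and 11 of 30 of the cytosolic large subunit (2.51 expected, adjusted p = 9.46e-04), whereas the term for the whole ribosome did not pass (20 of 140, 11.71 expected, adjusted p = 0.103). Rps12 rose by 0.72 (SE 0.12, adjusted p = 0.0081). The table places the probe sets of Rpl3 and Rpl41, both in the large subunit term, on chromosomes X and 14, away from these genes in the annotation. Of 1149 terms tested per direction, 99 passed for higher and 12 for lower genes.

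Among lower genes the Z disc (16 of 59, 3.63 expected, adjusted p = 2.41e-04), the T-tubule (10 of 29, 1.79 expected, adjusted p = 0.00116) and glycogen metabolism (9 of 28, 1.72 expected, adjusted p = 0.00415) were enriched, beside the macrophage marker median of 1.91. The sarcomere term did not pass (5 of 21, 1.29 expected, adjusted p = 0.263). Homer1, a scaffold of calcium channels, fell by 1.25 on the log2 scale (SE 0.12, adjusted p = 0.0023). Prkaa2, the catalytic subunit of the energy-sensing kinase AMPK that prevails in muscle, was at -0.93 (SE 0.12, adjusted p = 0.0038) and Mylk2, the skeletal myosin light chain kinase, at -0.93 (SE 0.11, adjusted p = 0.003). Epm2a, which encodes the glycogen phosphatase laforin, was at -0.79 (SE 0.11, adjusted p = 0.0044) and Gsk3b, which encodes a kinase of glycogen synthase, at -0.60 (SE 0.10, adjusted p = 0.0078).

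Single arrays carried signals that the genotypes do not share. Ucp1, the uncoupling protein of brown fat, read 8.88 in control 1 and 8.04 in knockout 3, against 2.32 to 3.72 on the other arrays, and Cidea read 6.42 and 5.90 there. The slow fibre genes Myh7 and Myl3 read 7.67 and 7.28 in control 3 but 2.48 and 2.80 in control 1, and 4.97 and 4.61 in knockout 1. The Y-linked genes Ddx3y and Eif2s3y were lowest in control 1, at 7.37 and 4.64, and highest in control 2, at 8.44 and 6.36. Both thus had signal on all 6 arrays, while Xist lay between 2.01 and 2.29, near the antigenomic background. These values argue against a female sample on any of the arrays. The labels name no muscle and no sex.

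Within 5 Mb of Sidt2, 12 of 85 tested genes had passed, or 14.1%, against 1916 of 13575 elsewhere, also 14.1% (Fisher's exact test, two-sided p = 1).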
